A study of Mus musculus with 7 samples.

How the data were processed

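RNA-seq was measured in 4 libraries of mouse embryonic fibroblasts in Stage 1 reprogramming medium, 2 given DMSO and 2 given R406, and CUT&Tag for FLAG-tagged Nfatc1 in 3 libraries, 1 with DMSO, 1 with R406 and 1 blank without primary antibody. Groups and replicate numbers were taken from the sample titles. The blank library was not analysed here.

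For RNA-seq, the authors deposited a table of TPM per gene and 1 file per library, and the values of all 4 single files were equal to the columns of the table. Per the labels' protocols, libraries were made from total RNA with an NEBNext Ultra kit, which does not mark strand. Per the submitters' processing notes, the tools included HISAT2 2.1.0 and StringTie 2.0 on mm10. The role of each tool, the annotation and the handling of reads that fit several genes are not given in the sources used here. StringTie spreads such reads over gene models, so values of near-identical genes are uncertain, and reads of overlapping or antisense genes cannot be told apart without strand. TPM has the same fixed sum in each library, so a rise of some transcripts lowers the values of all others, and read depth cannot be recovered. An exact 0 may be a failed estimate, and such values are described as listed at 0.

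For CUT&Tag, the authors deposited 1 list of peaks per library, with a fold enrichment, a −log10 p-value, a −log10 q-value and a score for each peak. Per the submitters' processing notes the tools included Bowtie2 2.2.5 and MACS2 2.1.2 on mm10, together with ChIPseeker, HOMER and deepTools. Whether the blank served as control, the limit used in calling and the handling of duplicate reads are not given in the sources used here. In the deposited lists the score equalled 10 times the −log10 p-value, cut to a whole number, in 100.0% of peaks, and the lowest −log10 p-value was 5.03 and 5.0. In both lists 94.2% and 94.5% of peaks had a fold that was a whole number of pileup steps over one fixed background, within 0.002 of a step, which gave the background pileup of each library.

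The table listed 53715 genes, of which 53620 had a symbol in the gene table used. Genes with a mean of at least 1 TPM over the 4 libraries were kept (13929 genes). TPM was not scaled further. R406 was compared with DMSO by limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Replicate numbers did not enter the model, because no label says that a number marks a shared culture.

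Gene lists, 26 in number, were fixed before the data were examined. They covered the Syk, calcineurin and NFAT pathway; NFAT targets; serine, glycine and one-carbon metabolism; methionine, transsulfuration and hydrogen sulphide metabolism; glycolysis; oxidative phosphorylation and the TCA cycle. Lists of cell identity covered pluripotency, extraembryonic endoderm, fibroblast and mesenchyme, smooth muscle and contractile, epithelium, two-cell-like, macrophage, endothelium, adipocyte, striated muscle, neural and glial, and erythroid genes. Lists of cell state covered cell cycle, p53 with senescence and secreted inflammatory factors, ATF4, the aryl hydrocarbon receptor, oxidative stress and NRF2, interferon, cholesterol synthesis, and immediate early genes. The 23 lists with at least 4 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over these lists. Camera was run again with an estimated correlation, under which 0 lists passed. That version rests on the 2 residual degrees of freedom of the fit, so it had little power over 23 lists. The interferon list had an estimated correlation of −0.0155, below the preset, yet an adjusted p of 0.478 there. The loss of the interferon call therefore does not show that correlation between genes undid it. Estimates were also low for the Syk pathway (0.00351) and the aryl hydrocarbon receptor list (−0.0448). They were far above the preset for endoderm (0.640), epithelium (0.713), cell cycle (0.556) and contractile genes (0.758), among others. If those estimates hold, the preset camera p-values of these lists are too small. Limma's fry, also chosen beforehand in a directional and a mixed form, was adjusted over the same 23 lists. Fry below means the directional form unless the mixed form is named. The mixed form asks whether members changed in either direction. It judges each list alone, while 3736 of the 13929 tested genes had an unadjusted limma p under 0.05. Passing it therefore does not set a list apart from other genes. Calls within a list were counted over all genes tested and adjusted over the list alone. Genes were named by a fixed rule: up to 12 per direction with the largest log2 change among calls, with a mean of at least 5 TPM in the higher group, groups that did not overlap and no predicted or pseudogene symbol; up to 4 members per list with the smallest p; and a fixed set of pathway, metabolic and identity genes. Peaks were named if they ranked in the first 5 by fold on chromosomes 1 to 19 and X in either library, or lay near an end of a gene named for its change or in the fixed set. Results for some genes that this rule would name are not reported here.

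Peaks were compared by overlap of at least 1 bp with bedtools 2.31.1, with Wilson 95% intervals for shares. Peaks were joined to genes by RefSeq gene spans of assembly GRCm38.p6, the assembly that mm10 names, and 13506 of the 13929 tested genes (97.0%) had a position. Because the gene table gives no strand, start sites could not be placed, and the window of 3000 bp around the start site that was chosen beforehand was replaced by a window of 3000 bp around both ends of the gene span. Calls and peaks were set against each other by two-sided Fisher's exact tests, 8 in all. A search for NFAT motifs at summits was left out, because no genome sequence was used here.

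Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, quantile normalization, median centring, limma without trend or with a robust prior, the replicate number as a block, leaving out each library, 50% overlap of both peaks, a q-value limit of 0.0001, equal numbers of top peaks, and windows of 1000 bp. Added after the data were seen were the removal of mitochondrial, ribosomal protein and Gm genes with rescaling, peaks anywhere in the gene span, and thinning of the R406 pileups to the background of the DMSO library. The RNA test was tested on simulated data with the real gene means, in 10 simulations of 13929 genes. Spreads were drawn from the prior that limma fitted, with independent normal noise, as the test itself assumes. With 200 changed genes the test recovered 0.294%, 60.8% and 92.9% of log2 changes of 1, 2 and 4, with 4.46% false calls. With 2000 changed genes it recovered 44.2%, 91.7% and 99.0%, with 4.14% false calls. No effect shared by replicate numbers and no failed estimates were simulated, so these rates of false calls need not hold in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.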

Results

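R406, an inhibitor of the kinase Syk and the active metabolite of fostamatinib, was tested on mouse fibroblasts in an early phase of chemical reprogramming, in which small molecules take the place of introduced reprogramming genes. The study's title names Syk, calcineurin and NFAT as one signalling axis, together with metabolism and hydrogen sulphide. Calcineurin is a calcium-dependent phosphatase, and NFAT proteins are transcription factors that enter the nucleus once calcineurin has dephosphorylated them. Embryonic fibroblasts were taken at embryonic day 13.5 from OG2 mice, which carry a green fluorescent reporter driven by Pou5f1. Cells were grown in Stage 1 medium, which holds basic fibroblast growth factor, vitamin C and small molecules such as valproic acid, CHIR99021, forskolin, AM580 and EPZ004777, under a protocol of 12 days. RNA-seq was run on 2 libraries of cells given the solvent DMSO and 2 libraries of cells given R406. CUT&Tag, which cuts DNA where an antibody is bound, was run with an anti-FLAG antibody on cells that expressed FLAG-tagged Nfatc1 and had received DMSO or R406 for 4 days, with 1 library for each condition. A further library made without the primary antibody was not analysed here. The day of RNA harvest and the concentration of R406 are not given in the sources used here.

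Expression values were in the unit TPM, the share of a transcript in a fixed total, which keeps no depth, so the number of reads behind each value is unknown. Between 13537 and 14045 genes reached 1 TPM in a library. Pearson's r of log2(TPM + 1) across genes, which are not independent replicates, was 0.974 between the DMSO libraries, 0.971 between the R406 libraries and 0.916 to 0.942 across conditions. The first principal component held 66.9% of the variance and separated DMSO from R406. Ribosomal protein genes took 15.8% and 17.5% of TPM in the DMSO libraries and 21.5% and 25.1% in the R406 libraries, while mitochondrial genes took 10.5% and 14.2% against 6.72% and 10.3%. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The RNA test, the gene lists and the rule for naming genes were fixed before the data were examined, while the windows that join peaks to genes were set afterwards, because the gene table gives no strand.

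R406-treated cells held far less RNA of a lysozyme, several chemokine and 2 proliferin genes, and far more RNA of a prostaglandin synthase, a collagen and an acute-phase gene. Lyz2, the lysozyme of macrophages, fell from 193 ± 19.7 to 3.59 ± 0.374 TPM (mean ± SD, n = 2 libraries per group here and below), a log2 change of −5.40. The monocyte-attracting chemokine Ccl8 fell from 1238 ± 2.78 to 54.3 ± 10.9 TPM, and Areg, a ligand of the epidermal growth factor receptor, from 42.7 ± 13.0 to 0.920 ± 0.0117 TPM. In the other direction, the prostaglandin synthase gene Ptgds rose from 0.116 ± 0.0273 to 47.1 ± 14.5 TPM, a log2 change of 5.40. The basement membrane collagen gene Col15a1 rose from 1.76 ± 0.307 to 50.3 ± 4.71 TPM, and the acute-phase gene Saa3 from 38.9 ± 0.224 to 736 ± 107 TPM. Other large rises were those of Igsf1, Oit1, Gkn2, the vasopressin gene Avp, the mannose-binding lectin gene Mbl2, Nrgn, the calretinin gene Calb2, the antitrypsin gene Serpina1e and Sprr2a1, with log2 changes of 3.43 to 4.41. Serpina1e and Sprr2a1 have near-identical paralogs, so their values are uncertain. Other large falls were those of the proliferin genes Prl2c3 and Prl2c2, which are near-identical to each other, the platelet chemokine genes Pf4 and Ppbp, the chymase gene Cma2, and Clec4n, Ccl6 and Ms4a6d, with log2 changes of −5.38 to −3.96. Grp, which encodes gastrin-releasing peptide, stood at 21.6 and 11.4 TPM in the DMSO libraries and was listed at 0 in both R406 libraries.

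Of 13929 genes tested with limma on log2(TPM + 1), 593 were higher and 564 lower in R406 at a Benjamini-Hochberg adjusted p of 0.05, and 3736 had an unadjusted p under 0.05. A log2 change on this scale understates the change of genes with low values. The 12 largest rises had adjusted p of 0.00785 to 0.0190, the 12 largest falls 0.00785 to 0.0165, and each of these 24 genes stayed past the threshold when any single library was left out. The libraries of the 2 groups did not overlap in 7809 genes (56.1%), where chance gives 33.3%. The counts rested on single libraries: 159 higher and 158 lower without DMSO replicate 1, 383 and 335 without DMSO replicate 2, and 914 and 496 without R406 replicate 2. With all 4 libraries, 850 were lower with quantile normalization, 900 higher with median centring, and 311 higher and 332 lower among genes with a mean of at least 5 TPM. The counts were 0 and 0 with no filter on low values (27879 genes tested, 5394 with an unadjusted p under 0.05), and 1163 and 999 without mitochondrial, ribosomal protein and predicted Gm genes, an alternative chosen after the data were seen.

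**Figure D1:**
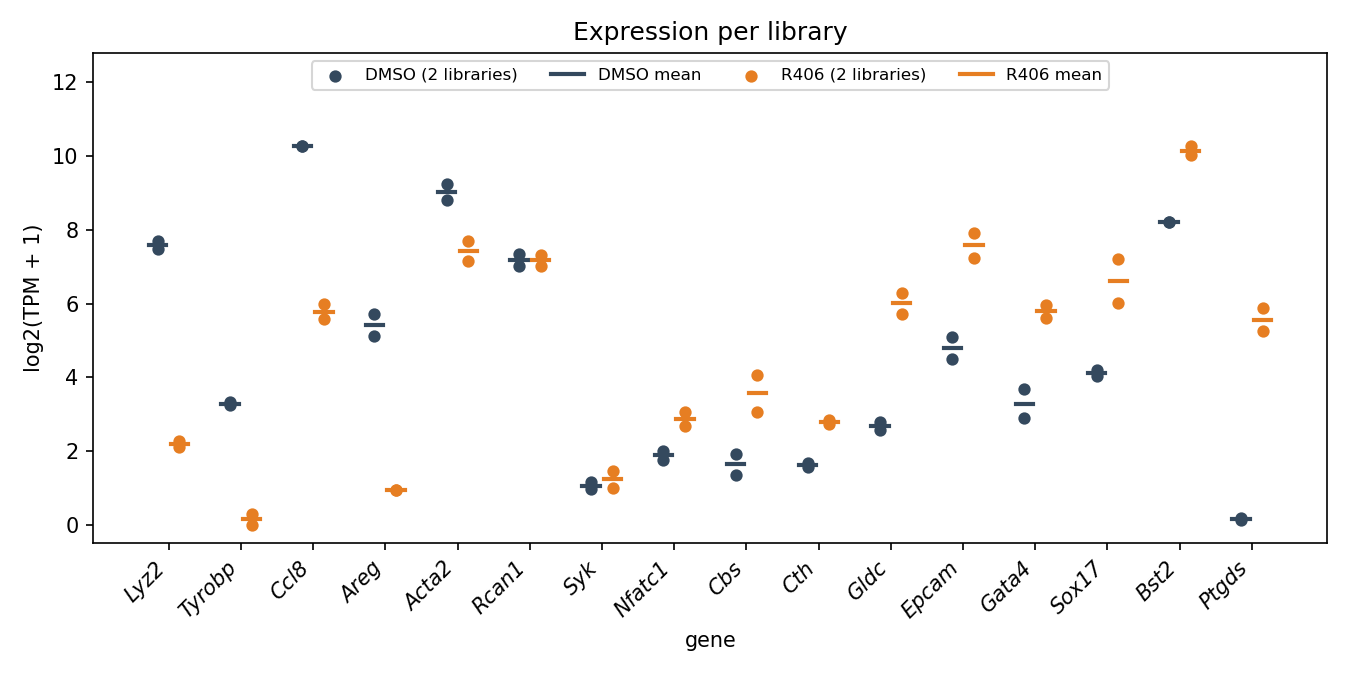
Expression of 16 named genes as log2(TPM + 1), with 1 point per library and a bar at the mean of the 2 DMSO (dark) or 2 R406 (orange) libraries. Lyz2, Tyrobp, Ccl8 and Areg lie lower in R406, Ptgds, Gldc, Epcam and Gata4 lie higher, and Rcan1 and Syk overlap between the groups.

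Macrophage genes fell nearly as a block, while markers of other minor cell types moved in both directions. Of 11 tested macrophage genes, 10 fell over all genes tested and 10 when adjusted over the list alone, with a list median of −2.57. Tyrobp, an adaptor of myeloid receptors that signals through Syk, fell from 8.79 ± 0.502 to 0.115 ± 0.163 TPM (log2 −3.14, limma adjusted p = 0.0110). The complement gene C1qc fell from 7.47 ± 1.28 to 0.239 ± 0.183 TPM and Fcer1g, a subunit of Fc receptors, from 7.95 ± 1.78 to 0.337 ± 0.0700 TPM. The exception was Cd14, named after its values were seen, at 11.9 TPM in DMSO and 14.8 TPM in R406 (log2 0.32, adjusted p = 0.516). Camera with its preset correlation gave the macrophage list an adjusted p of 7.46e-09, and adjusted p = 0.478 with an estimated correlation. The estimated version rests on 2 residual degrees of freedom and had little power, here and below. Limma's fry gave the list an adjusted p of 0.0259. Among 5 tested endothelial genes 1 rose, the adhesion gene Esam, from 1.20 ± 0.0297 to 9.08 ± 2.92 TPM, and 1 rose when adjusted over the list alone (median 0.58, camera adjusted p = 0.159). Of 5 neural and glial genes 1 rose, Stmn2, from 10.3 ± 3.01 to 53.9 ± 7.55 TPM, while 1 rose and 4 fell when adjusted over the list alone (median −0.90, camera adjusted p = 0.223). None of 7 striated muscle genes passed limma's threshold, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 (median 0.20, camera adjusted p = 0.435). Lpl, a lipoprotein lipase, was the 1 of 3 adipocyte genes that rose, from 2.56 ± 0.528 to 15.1 ± 3.38 TPM, and 1 rose and 2 fell when adjusted over the list alone. Both tested erythroid genes, Hba-a1 and Hba-a2, rose over all genes and when adjusted over the list alone (log2 2.41 and 2.18). These are near-identical globin genes, and both lost their calls without DMSO replicate 1 (adjusted p = 0.0663 and 0.0605). Without R406 replicate 2, 2 endothelial genes and 1 striated muscle gene were called, without DMSO replicate 2 or R406 replicate 1, 1 neural gene also fell, and without DMSO replicate 2, 1 adipocyte gene also fell.

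**Figure D2:**
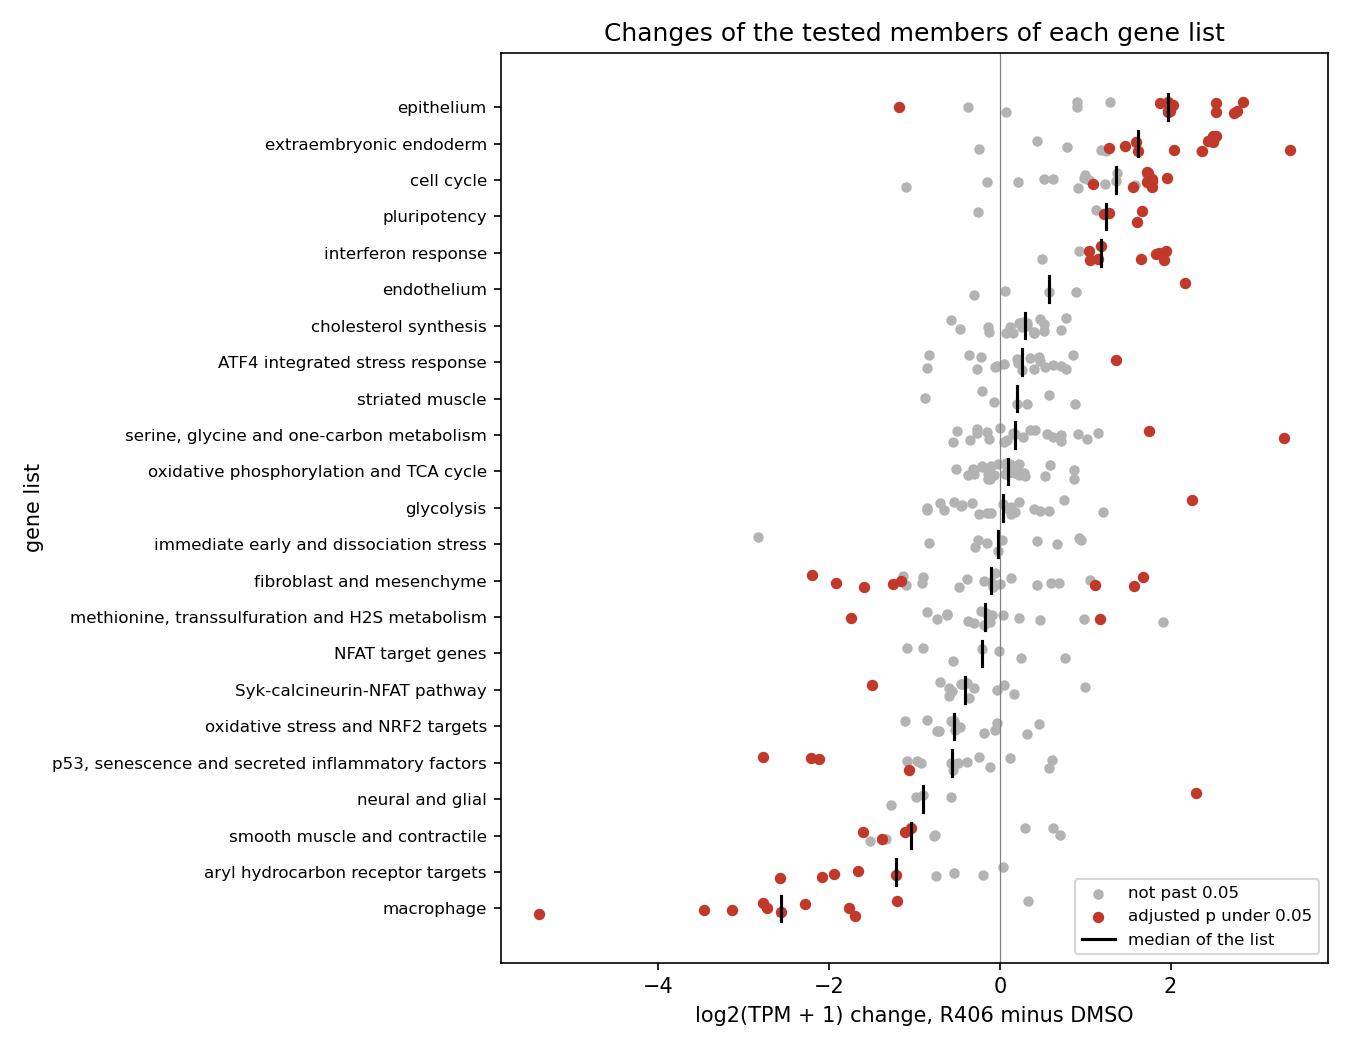
Log2(TPM + 1) change, R406 minus DMSO, of each tested member of the 23 gene lists with at least 4 tested members, with 1 point per gene, red where the adjusted p was under 0.05, and a black bar at the list median. Macrophage genes lie at the far left with a median of −2.57, and epithelial and extraembryonic endoderm genes lie at the right with medians of 1.97 and 1.61.

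Extraembryonic endoderm and epithelial genes were higher in the R406 libraries. Of 17 tested endoderm genes, 11 rose and 0 fell over all genes, and 15 rose when adjusted over the list alone, with a median of 1.61. Gata4, which encodes a transcription factor of endoderm, rose from 9.15 ± 3.83 to 54.7 ± 10.0 TPM (adjusted p = 0.0222). Cited1, a transcriptional co-regulator, rose from 59.0 ± 3.21 to 672 ± 329 TPM, and Sox17 rose from 16.4 ± 1.21 to 105 ± 57.7 TPM (log2 2.49). Gata6 stood at 4.43 ± 0.659 and 6.54 ± 2.73 TPM (adjusted p = 0.445). Of 18 tested epithelial genes, 12 rose and 1 fell over all genes, against 14 and 1 when adjusted over the list alone, with a median of 1.97. The cell adhesion gene Epcam rose from 27.3 ± 8.17 to 194 ± 61.9 TPM and the tight junction gene Cldn7 from 5.56 ± 0.434 to 47.8 ± 18.6 TPM. The desmosome gene Dsp, named after its values were seen, fell from 15.2 to 6.24 TPM. Only 6 of 24 pluripotency genes were expressed highly enough to be tested. Of these, 4 rose over all genes and 5 when adjusted over the list alone (median 1.2): Tbx3, Lin28a, Sall4 and Klf5, with log2 changes of 1.22 to 1.67. All are also expressed outside pluripotent cells, and Sall4 is in the endoderm list too. Pou5f1, at 0.867 and 0.178 TPM in DMSO and listed at 0 in both R406 libraries, was not tested, nor was any of the 9 two-cell-like genes.

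Camera with the preset correlation gave adjusted p = 6.91e-10 for endoderm, 7.26e-08 for epithelium and 0.00151 for pluripotency. With an estimated correlation it gave adjusted p = 0.545, 0.596 and 0.545. The correlations were estimated at 0.640, 0.713 and 0.205, against the preset of 0.01, so the preset p-values may be too small. None of these lists passed limma's fry (adjusted p = 0.107, 0.143 and 0.111). The macrophage list median in the same libraries was −2.57. Without DMSO replicate 1 the calls shrank to 4 endoderm, 3 epithelial and 0 pluripotency genes, and Sox17 had an adjusted p of 0.0725. Without DMSO replicate 2 they were 8 epithelial and 1 pluripotency genes, without R406 replicate 1 they were 2 pluripotency genes. Klf5 lost its call in each leave-out (adjusted p of 0.0536 to 0.221), Sall4 in all but that without R406 replicate 2, and Tbx3 without DMSO replicate 2 (0.0612). Dsp passed only with all 4 libraries or without R406 replicate 1.

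Cell cycle and interferon genes were higher in R406, and p53-related and secreted inflammatory genes were lower. Of 24 tested cell cycle genes, 10 rose and 0 fell over all genes, and 21 rose and 1 fell when adjusted over the list alone, with a median of 1.36. Cdc20, an activator of the anaphase-promoting complex, rose from 5.07 ± 0.0785 to 19.2 ± 2.81 TPM, and the mitotic kinase gene Plk1 from 2.1 ± 0.0114 to 9.72 ± 2.38 TPM. Of 11 tested interferon response genes, 9 rose over all genes and 11 when adjusted over the list alone, with a median of 1.18. Bst2, which tethers budding virus particles, rose from 294 ± 1.15 to 1136 ± 147 TPM, and the ubiquitin-like Isg15 from 9.87 ± 0.279 to 37.9 ± 7.36 TPM. Of 16 tested genes in the list of p53, senescence and secreted inflammatory factors, 4 fell and 0 rose over all genes, and 6 fell when adjusted over the list alone, with a median of −0.56. The collagenase gene Mmp13 fell from 12.4 ± 0.997 to 1.91 ± 0.182 TPM and the chemokine gene Ccl7 from 329 ± 32.5 to 75.1 ± 13.7 TPM. Mdm2, the ubiquitin ligase of p53, fell from 101 ± 0.0861 to 47.6 ± 2.70 TPM (adjusted p = 0.0338).

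The preset camera test gave adjusted p = 6.91e-10 for cell cycle, 1.75e-08 for interferon and 0.00163 for the p53 list. With an estimated correlation these were 0.545, 0.478 and 0.478. The correlations were estimated at 0.556, −0.0155 and 0.0197, so the preset p-value of the cell cycle list may be too small. Limma's fry gave adjusted p = 0.107, 0.00971 and 0.0425, so the cell cycle list did not pass it. Beside these groups, the macrophage median was −2.57 and the ribosomal protein share was higher in both R406 libraries than in either DMSO library. Without DMSO replicate 1, 0 cell cycle and 0 interferon genes passed limma's threshold (Cdc20, Plk1, Bst2 and Isg15 at adjusted p of 0.0603 to 0.0653), and without DMSO replicate 2, 4 interferon genes did. Cell cycle calls numbered 16 without R406 replicate 2, and Mdm2 lost its call in each of the 4 leave-outs (adjusted p of 0.0553 to 0.186).

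In the Syk, calcineurin and NFAT pathway 1 gene passed limma's threshold. Of 14 tested members, 1 fell and 0 rose, both over all genes and when adjusted over the list alone, with a median of −0.41. An unadjusted p under 0.05 was reached by 5 members, 1 higher and 4 lower. Members without a call cannot be read as unchanged. Itpr1, a receptor that releases calcium from the endoplasmic reticulum, fell from 16 ± 1.98 to 5.03 ± 0.313 TPM (log2 −1.50, adjusted p = 0.0221). Syk itself was low, at 1.1 ± 0.196 TPM in DMSO and 1.38 ± 0.516 TPM in R406 (log2 0.17, adjusted p = 0.705). Nfatc1 stood at 2.70 ± 0.405 and 6.40 ± 1.35 TPM (log2 0.99, adjusted p = 0.0659), Nfatc3 at 9.76 ± 1.78 and 7.18 ± 0.693 TPM, and Nfatc4 at 25.8 ± 7.17 and 26.2 ± 0.425 TPM. Nfatc2, at 0.404 and 0.768 TPM, was too low to be tested. The calcineurin genes Ppp3ca, Ppp3cb and Ppp3r1 had log2 differences of −0.56 to −0.37, with adjusted p of 0.128 to 0.285. None of 7 tested NFAT target genes passed over all genes, while 3 had an unadjusted p under 0.05. When adjusted over the list alone, the bone-resorption phosphatase gene Acp5 rose (32.2 to 55.6 TPM) and the cyclooxygenase gene Ptgs2 fell (15.5 to 7.81 TPM). Rcan1 encodes a calcineurin inhibitor and is used as a readout of NFAT activity. It measured 144 ± 22.8 TPM in DMSO and 144 ± 22.2 TPM in R406 (limma adjusted p = 0.992). This gene-level value sums all transcripts of Rcan1, so it cannot show whether a given transcript form changed.

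The macrophage list had a median of −2.57 in the same libraries. The pathway list did not pass limma's fry (adjusted p = 0.107). Fry's mixed form, which allows either direction, gave adjusted p = 0.00442 for the pathway list and 0.00456 for the target list. Camera gave the pathway list an adjusted p of 0.0446, with adjusted p = 0.545 with an estimated correlation, and the target list 0.545 (median −0.20). The pathway call was lost on leaving out any 1 library, with adjusted p of 0.0879 (DMSO replicate 1), 0.114 (DMSO replicate 2), 0.134 (R406 replicate 1) and 0.0740 (R406 replicate 2). Itpr1 lost its call without DMSO replicate 1 (0.0697) or 2 (0.0712), and without R406 replicate 2 both Nfatc1 (0.0430) and 1 NFAT target gene passed.

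Few metabolic genes passed the test, among them genes of glycine breakdown, hydrogen sulphide metabolism and lactate transport. Of 25 tested serine, glycine and one-carbon genes, 2 rose and 0 fell over all genes, and 3 rose when adjusted over the list alone, with a median of 0.18. The risers break down amino acids: Gldc, the decarboxylase of the glycine cleavage system, rose from 5.43 ± 0.613 to 64.6 ± 17.9 TPM (log2 3.33, adjusted p = 0.0125), and Tdh, threonine dehydrogenase, from 1.36 ± 0.446 to 7.01 ± 2.54 TPM (adjusted p = 0.0374). The serine synthesis genes Phgdh, Psat1 and Psph had log2 differences of 0.63, 0.72 and 0.71 with adjusted p of 0.327, 0.115 and 0.0879, and Shmt1, Shmt2 and Gcat had 1.02, 0.55 and 0.92 with 0.0897, 0.335 and 0.0855. Gnmt was too low to be tested. Of 18 tested genes of methionine, transsulfuration and hydrogen sulphide metabolism, 1 rose and 1 fell over all genes, and 3 rose and 4 fell when adjusted over the list alone, with a median of −0.18. Cth, which makes cysteine and can release hydrogen sulphide, rose from 2.08 ± 0.157 to 5.92 ± 0.294 TPM (log2 1.17, adjusted p = 0.0313), and Sqor, which oxidises hydrogen sulphide in mitochondria, fell from 9.12 ± 2.31 to 1.99 ± 0.463 TPM (log2 −1.75, adjusted p = 0.0275). Cbs, the first enzyme of transsulfuration, stood at 2.2 ± 0.881 and 11.6 ± 6.05 TPM (log2 1.92, adjusted p = 0.0591), and Mpst at 34.7 ± 4.05 and 48.6 ± 7.16 TPM (adjusted p = 0.236). In glycolysis, 1 of 23 tested genes rose, over all genes and when adjusted over the list alone: the lactate transporter gene Slc16a3, from 8.23 ± 2.28 to 42.4 ± 5.99 TPM (adjusted p = 0.0183). None of 32 oxidative phosphorylation and TCA cycle genes passed limma's threshold over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05 and a median of 0.09.

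Beside the metabolic genes, the macrophage median was −2.57, the endoderm and epithelium medians were 1.61 and 1.97, and ribosomal protein genes took 21.5% and 25.1% of TPM in R406 against 15.8% and 17.5% in DMSO. The serine and glycine list did not pass limma's fry (adjusted p = 0.323). Fry's mixed form gave adjusted p = 0.0209 for serine and glycine, 0.00703 for methionine, 0.0209 for glycolysis and 0.195 for oxidative phosphorylation. Camera gave the serine and glycine list an adjusted p of 0.0322 (adjusted p = 0.736 with an estimated correlation). The methionine, glycolysis and oxidative phosphorylation lists had camera adjusted p of 0.560, 0.940 and 0.512. The serine and glycine call was lost without DMSO replicate 2 (0.0788) or R406 replicate 1 (0.0926). Without DMSO replicate 1 the calls of Tdh (0.106), Cth (0.150) and Sqor (0.0792) were lost. Cth was also lost without DMSO replicate 2 (0.0893) or R406 replicate 1 (0.0579), whereas Cbs passed without R406 replicate 1 (0.0459) or 2 (0.00464), and without R406 replicate 2 calls were made for 4 serine and glycine, 4 methionine, 2 glycolysis and 1 oxidative phosphorylation genes.

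Targets of the aryl hydrocarbon receptor, a sensor of foreign and dietary compounds, fell in R406. Of 9 tested targets, 5 fell over all genes and 7 when adjusted over the list alone, with a median of −1.22. The cytochrome gene Cyp1a1 fell from 2.84 ± 0.959 to 0.193 ± 0.0845 TPM and Tiparp, an ADP-ribosyltransferase gene, from 19.7 ± 1.72 to 7.90 ± 0.0202 TPM (adjusted p = 0.0284 and 0.0290). Ugt1a6a and Ugt1a7c also fell, and these share exons, so their values are not separate. None of 14 oxidative stress and NRF2 target genes passed over all genes, 7 had an unadjusted p under 0.05, and 3 fell when adjusted over the list alone, with a median of −0.53: the cystine transporter gene Slc7a11 (5.60 to 2.66 TPM), Txnrd1 (195 to 89.6 TPM) and Gclc (37.2 to 22 TPM). Of 21 genes of the ATF4 stress response, 1 rose over all genes and 0 when adjusted over the list alone, with a median of 0.26: the hormone gene Fgf21, from 0.789 ± 0.149 to 3.68 ± 1.34 TPM (adjusted p = 0.0480). None of 20 cholesterol synthesis genes passed over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and the median was 0.29, with Dhcr7 at 40.8 and 68.0 TPM (adjusted p = 0.0839).

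In the same libraries the macrophage median was −2.57, the endoderm and epithelium medians were 1.61 and 1.97, and the ribosomal protein share was 21.5% and 25.1% in R406 against 15.8% and 17.5% in DMSO. Camera gave adjusted p = 0.182 for ATF4. It gave 0.000225 for the aryl hydrocarbon receptor list, 0.0273 for NRF2 and 0.0495 for cholesterol synthesis. With an estimated correlation those were 0.478, 0.717 and 0.671. Limma's fry gave the same lists adjusted p = 0.0365, 0.184 and 0.294. Without DMSO replicate 1, 0 aryl hydrocarbon receptor targets passed limma's threshold (Cyp1a1 at 0.0603, Tiparp at 0.113), Tiparp was also lost without DMSO replicate 2 (0.129), and Fgf21 was lost without DMSO replicate 1 (0.142), DMSO replicate 2 (0.0735) or R406 replicate 1 (0.0599). The NRF2 list was lost without DMSO replicate 1 (0.0966) or R406 replicate 1 (0.0950; 1 gene then fell), the cholesterol list in each leave-out (0.0879 to 0.208), and the ATF4 list passed without DMSO replicate 1 (0.0257).

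Fibroblast genes moved in both directions, and contractile genes fell. Of 25 tested fibroblast and mesenchyme genes, 3 rose and 5 fell over all genes, and 4 rose and 7 fell when adjusted over the list alone, with a median of −0.11. The calcium-binding protein gene S100a4 fell from 261 ± 17.2 to 56.6 ± 11.4 TPM (log2 −2.2, adjusted p = 0.0165) and the fibrillin gene Fbn1 from 40.3 ± 7.08 to 9.81 ± 0.560 TPM, while the matrix gene Postn rose from 15.2 ± 0.346 to 50.7 ± 1.48 TPM. Of 11 tested smooth muscle and contractile genes, 4 fell over all genes, and 1 rose and 8 fell when adjusted over the list alone, with a median of −1.04. Acta2, smooth muscle actin, fell from 527 ± 112 to 174 ± 45.3 TPM (log2 −1.60, adjusted p = 0.0376), and Actg2, Tpm1 and Lmod1 fell with log2 changes of −1.38, −1.11 and −1.04. None of 11 immediate early and dissociation stress genes passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The direction of that list differed by measure, with a median of −0.02, a mean of −0.13 and an upward camera result (adjusted p = 0.958). Junb, named after its values were seen, had the lowest log2 difference of the list (−2.84, adjusted p = 0.413) and was listed at 0 in R406 replicate 2, which pulls the mean down.

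These changes came with a macrophage median of −2.57 and an epithelium median of 1.97. Camera gave the contractile list an adjusted p of 0.00895, with adjusted p = 0.717 with an estimated correlation, and the fibroblast list 0.335. The correlation of the contractile list was estimated at 0.758, so its preset p-value may be too small. The contractile list did not pass limma's fry (adjusted p = 0.151). Fry's mixed form gave adjusted p = 0.0209 for the contractile and 0.00442 for the fibroblast list. Without DMSO replicate 1 only S100a4 of these lists passed limma's threshold (Postn 0.0653, Fbn1 0.0572, Acta2 0.142), without DMSO replicate 2 the fibroblast list had 4 calls and Acta2 and Actg2 were lost (0.0565 and 0.0764), without R406 replicate 2 Acta2 was lost (0.0515), and Tpm1 and Lmod1 were lost in each leave-out. In the immediate early list, 1 gene, Junb, fell without R406 replicate 1 (0.000391), and without R406 replicate 2 the difference of Junb was 0.14 and 2 other genes rose.

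FLAG-tagged Nfatc1 gave peaks in both CUT&Tag libraries, and more of them with R406. The DMSO library had 21246 peaks covering 12.5 Mb and the R406 library 36885 peaks covering 22.8 Mb, with median widths of 481 and 484 bp. With at least 1 bp of overlap, 15515 of the DMSO peaks (73.0%, 95% Wilson interval 72.4 to 73.6) met an R406 peak, and 15276 of the R406 peaks (41.4%, 40.9 to 41.9) met a DMSO peak. Of 13506 tested genes with a RefSeq position, 5592 (41.4%, 40.6 to 42.2) had a DMSO peak within 3000 bp of either end of the gene, 8011 (59.3%, 58.5 to 60.1) had an R406 peak, and 5141 had both. The intervals cover counting error only, and with 1 library per condition the differences have no replicate check and were not tested. The background pileup recovered from the fold values was 0.373 in the DMSO library and 0.581 in the R406 library, a ratio of 1.56, and the overlaps depended on the rule used, at 50.5% and 29.1% when a peak had to share 50% of both widths.

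**Figure D3:**
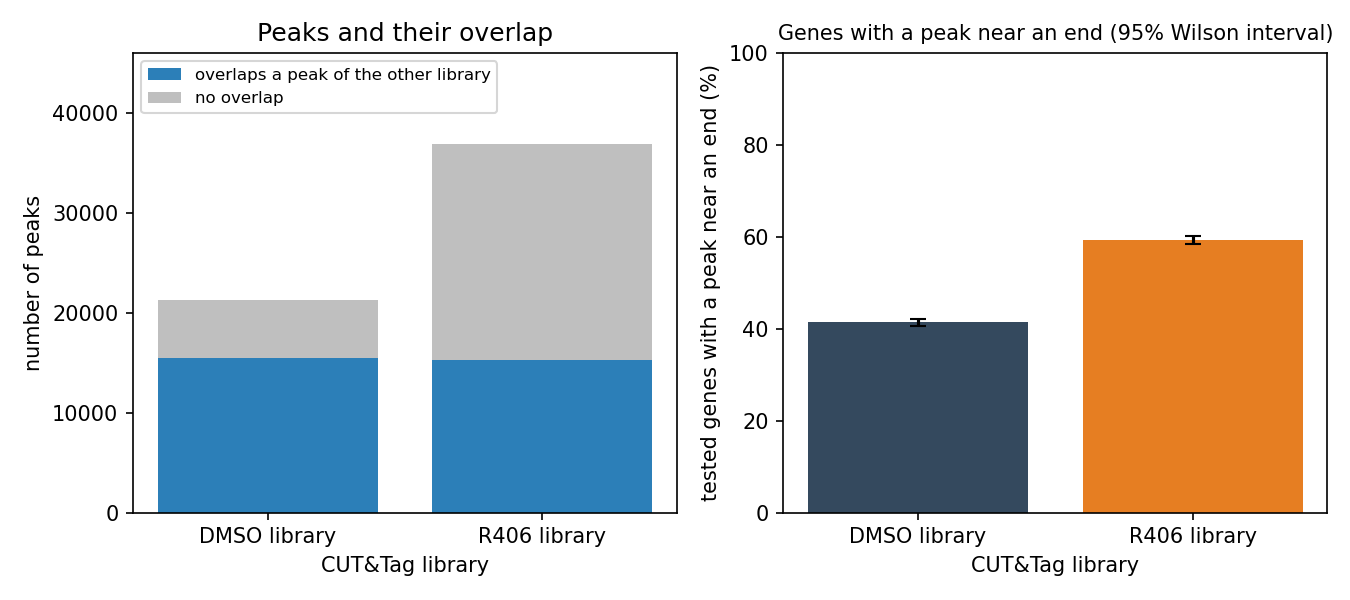
Left, number of peaks in the DMSO and R406 CUT&Tag libraries, split by overlap of at least 1 bp with a peak of the other library; right, percent of 13506 tested genes with a peak within 3000 bp of a gene end, with 95% Wilson intervals for counting error. The R406 library has more peaks (36885 against 21246) and more genes with a peak (59.3% against 41.4%), with 1 library per condition.

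A peak inside Rcan1 was among the highest on chromosomes 1 to 19 and X in either library. The gene-level RNA of Rcan1 measured 144 TPM in both conditions. On mm10 the Rcan1 gene spans chromosome 16 from 92391951 to 92466169, and the peak covered 92397618 to 92401488 in the DMSO library (fold enrichment 166) and 92397785 to 92401853 in the R406 library (237). The Rcan1 gene with 3000 bp on each side held 13 peaks in the DMSO library and 22 in the R406 library. Fold enrichments are the authors' own values, and peaks are ranked by them only within a list. In both libraries the highest fold on these chromosomes belonged to a narrow peak on chromosome 1, at 195241403 to 195241917 with DMSO (177) and 195241325 to 195241991 with R406 (414), and Cr2, the nearest named gene, ended 64523 and 64445 bp away. The third-ranked peak was also shared, on chromosome 4 at 47504626 to 47506058 (144) and 47504706 to 47505817 (234), 21393 and 21473 bp from Sec61b. Next on these chromosomes in the DMSO library came a peak on chromosome 3 at 151913695 to 151915160 (111), 76167 bp from Ptgfr, and a peak inside Wipi1 on chromosome 11 at 109592826 to 109594432 (104). Next in the R406 library came a peak at an end of Rheb on chromosome 5, 24841465 to 24843709 (228), and a peak 17802 bp from Otogl on chromosome 10, 107930181 to 107933959 (202). All 10 peaks overlapped a peak of the other library. Because the gene table used gives only whole gene spans, exons, introns and start sites were not assigned.

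**Figure D4:**
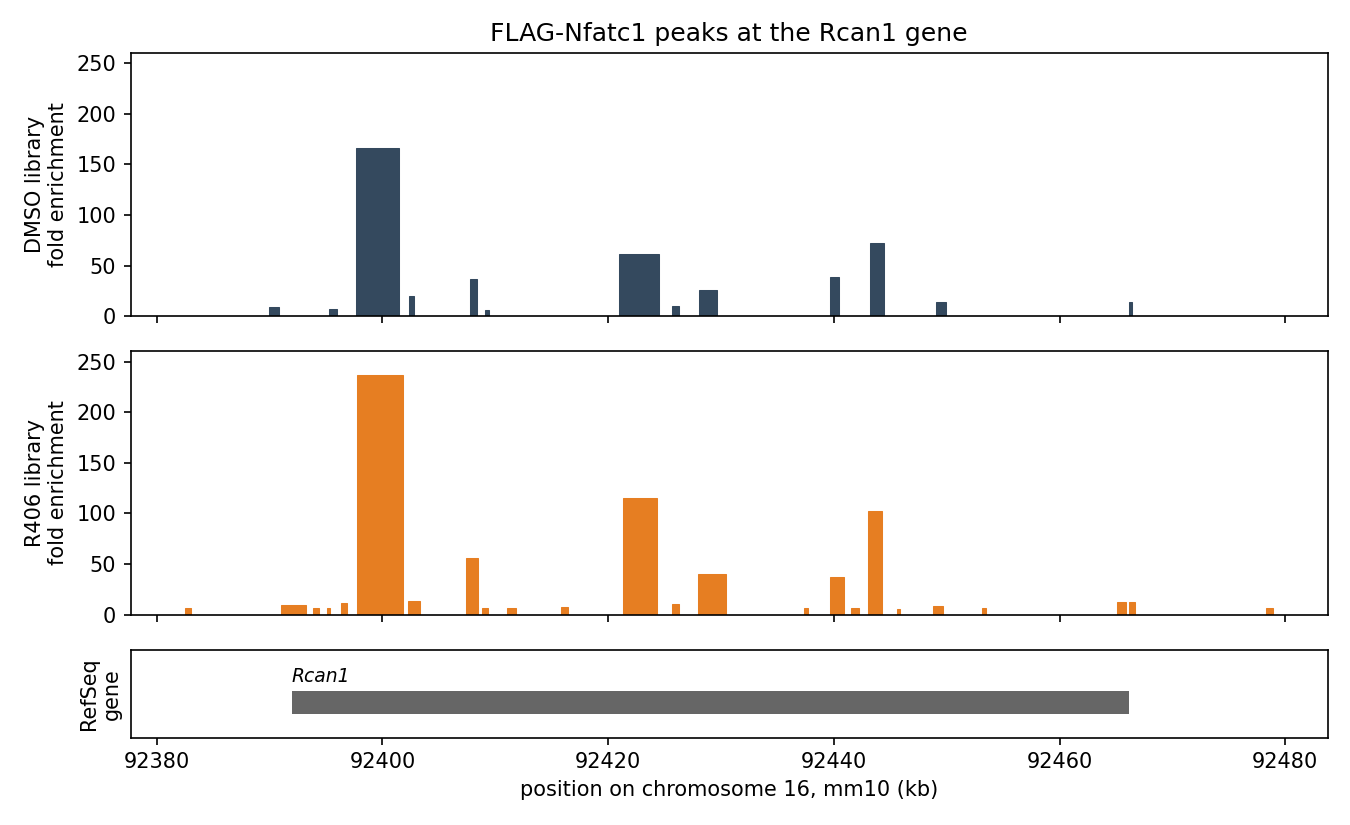
Fold enrichment, as given by the authors, of each peak at the Rcan1 gene against its position on chromosome 16 of mm10 in kb, for the DMSO library (top) and the R406 library (middle), with the RefSeq gene span as a bar at the bottom. The highest peak lies near the low-coordinate end of the gene in both libraries, at folds of 166 and 237, and most of the other DMSO peaks recur with R406.

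Peaks lay at several genes of the pathway itself. A peak just beyond the Syk gene (chromosome 13, 52582610 to 52648792) covered 52651531 to 52652686 in the DMSO library (fold 47.4) and 52651524 to 52652649 in the R406 library (88.6). An end of Nfatc4 on chromosome 14 carried a peak at 55822478 to 55825057 (48.8) and 55822568 to 55826012 (55.0). The Nfatc1 locus held 13 and 15 peaks, in cells that also carried an Nfatc1 transgene, whose DNA shares sequence with exons of the gene. Among metabolic genes, Mpst, Psat1, Psph, Shmt1 and Gcat had a peak near an end in both libraries, Cth and Phgdh only in the R406 list, and Cbs, Shmt2, Gnmt and Tdh had none in either. Gata4 had a DMSO peak near an end (chromosome 14, 63194938 to 63195965, fold 28.4), Gata6 and Lin28a had such peaks only in the R406 list, and Sall4, Sox17 and Pou5f1 had none. Of the 24 genes with the largest changes, only Col15a1, Avp, Calb2 and Ccl8 had a peak near an end in at least 1 library, with folds of 5.10 to 15.8. These differences between the lists were not tested.

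Genes that rose with R406 had a FLAG-Nfatc1 peak near an end less often than other genes. Among 579 genes called higher, 137 (23.7%, 20.4 to 27.3) had a DMSO peak within 3000 bp of an end, against 5455 of 12927 others (42.2%, 41.3 to 43.1), an odds ratio of 0.425 (two-sided Fisher's exact test, p = 7.87e-20, adjusted p = 2.1e-19 over 8 tests). Among 559 genes called lower, 213 (38.1%, 34.2 to 42.2) had such a peak, against 5379 of 12947 others (41.5%, 40.7 to 42.4), an odds ratio of 0.866 (Fisher's exact test, p = 0.114, adjusted p = 0.13). Genes are not independent replicates, and the RNA and CUT&Tag came from different cells. Genes called higher were by selection lower in DMSO, and the test did not match genes by their expression there. With peaks of the R406 library their odds ratio was 0.423 (Fisher's exact test, adjusted p = 4.32e-23). The blank library was not analysed, so signal that does not come from FLAG-Nfatc1 was not separated. For genes called lower, the odds ratio was 0.703 with peaks of the R406 library (adjusted p = 8.11e-05), and it turned to 1.29 (adjusted p = 0.00501) when peaks anywhere in the gene or within 3000 bp of it were counted, an alternative chosen after the data were seen.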

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

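None of the tests in this part was chosen before the data were seen, since peaks on unplaced sequence were looked at only because both lists held them. Peaks on scaffolds with no chromosome numbered 72 in the DMSO library and 66 in the R406 library, and they entered no comparison by gene. The highest lay on scaffold JH584304 in both libraries, at 58300 to 60731 with a fold enrichment of 137 in the DMSO library and at 58212 to 60790 with a fold of 197 in the R406 library. These stood out because the sequence is outside the main comparison. The blank library was not analysed here, so no level in control cells can be set beside them.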

How the results depend on the processing

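Chosen only after the results were seen were the removal of mitochondrial, ribosomal protein and Gm genes, the count of peaks in whole gene spans and the thinning of R406 pileups. No call of the 593 higher and 564 lower genes changed sign in any setting. With no filter, limma called 0 genes higher and 0 lower of 27879, and 0 list genes, with 5394 at an unadjusted p under 0.05; the cause was not tested. A filter of 5 TPM gave 311 and 332 of 9649 genes. Quantile normalization gave 850 lower, median centring 900 higher, and the removal of mitochondrial, ribosomal protein and Gm genes 1163 and 999, with 138 list genes; the cause was not tested. Leaving out 1 library, where the lone sample of its group is assumed to vary like the other group, gave 159 to 914 higher, 158 to 574 lower, 24 to 105 list genes and 9 to 11 called lists, against 89 genes and 13 lists with all 4 libraries. The median of all genes then moved to −0.139 without R406 replicate 1. Camera with an estimated correlation, with 2 residual degrees of freedom and little power, called 0 lists. Limma's directional fry passed only the interferon, macrophage, aryl hydrocarbon receptor and p53 lists (adjusted p of 0.00971 to 0.0425). Fry's mixed form passed all lists but oxidative phosphorylation, ATF4, immediate early and striated muscle (adjusted p of 0.195 to 0.505). Of 77 named genes called, 73 kept their call in every setting that tested them other than a leave-out or no filter (106 of 131 named genes were tested at 5 TPM), and 42 in every leave-out; no call reversed. In addition, quantile normalization ended the list call of the Syk pathway (adjusted p = 0.0508), a pseudocount of 0.1 that of cholesterol synthesis (0.0679), a filter of 5 TPM that of NRF2 (0.0671) while ATF4 then passed (0.0415), and the removal of gene classes those of the Syk pathway and cholesterol synthesis (both 0.0553).

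With the replicate number as a block, 2128 genes were higher, 2535 lower and 207 list genes called, all 593 and 564 calls were kept, and no list call changed. With 2 replicates per group the numbers alone do not pair the samples. The differences of replicate 2 from 1 correlated at 0.556 between the groups across genes, and the second principal component (26.7%) separated the numbers.

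Overlap of 50% of both peaks gave 50.5% of DMSO and 29.1% of R406 peaks shared, a q-value limit of 0.0001 gave 74.4% and 43.2%, equal numbers of top peaks 62.7% and 61.2%, and thinning 70.7% and 45.7%, against 73.0% and 41.4%. For genes called lower, the odds ratio of 0.866 was 0.703 with R406 peaks and reversed to 1.29 with peaks in whole gene spans, where long genes have more room for a peak; the cause was not tested. The NFAT motif search and its alternatives were not run, as no genome sequence was used here. Read depth behind the TPM values is unknown.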

Other observations

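The gene families and second marker lists here were chosen after the data were seen, as were the tests with values −0.015, −0.121 and −0.108, the overlap of top peaks and the expectation by expression level. Of 16 gene families put to 32 Fisher's exact tests against limma's calls, the smallest p was that of falling chemokines. Because the families were chosen with these same calls in view, their p-values are descriptive and do not test a family effect. Of 23 tested chemokines 10 fell (adjusted p = 2.49e-07) and 4 rose (0.0484), among them Cxcl14, from 155 to 792 TPM, and the rise did not pass without DMSO replicate 2 (0.0972) or R406 replicate 2 (0.336). Of 5 tested ligands of the epidermal growth factor receptor, all 3 that were called fell (Fisher's adjusted p = 0.00284). These were Areg, Ereg (31.1 ± 4.62 to 1.42 ± 0.304 TPM, n = 2) and Epgn (4.34 to 0.117 TPM). Tgfa was higher without passing (0.802 to 3.17 TPM, limma adjusted p = 0.0607), and Hbegf stood at 1.56 and 0.928 TPM (0.295). All 4 tested UDP-glucuronosyltransferases fell (adjusted p = 4.01e-05), including Ugt2b34, which lies outside the Ugt1a group with its shared exons (18.4 to 1.11 TPM). The other members, Ugt1a6a, Ugt1a7c and Ugt1a9, were counted as separate genes despite those exons, so this p-value is too small. Small proline-rich genes split, with 5 of 8 falling (Fisher's adjusted p = 4.33e-05) and 2 rising (0.114), and these paralogs share reads. The falls of these 4 families stayed past 0.05 without any single library, although without DMSO replicate 1 only 2 UDP-glucuronosyltransferases fell.

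In libraries where the endoderm, epithelium and macrophage medians were 1.61, 1.97 and −2.57, collagens rose in 9 of 31 cases (adjusted p = 4.01e-05), among them Col3a1 (233 to 701 TPM) and the minor collagens Col15a1, Col26a1 and Col8a2, while none fell. Claudins rose in 5 of 10 (adjusted p = 0.000186) while 1 fell, and keratins in 5 of 13 (0.00071) while Krt34 and Krt15 fell (log2 −2.57 and −2.13), and Sox factors in 4 of 12 (0.0049: Sox7, Sox14, Sox17 and Sox18). Some members of the claudin, keratin and Sox families are also in the epithelium or endoderm list. Without DMSO replicate 2 the collagen, claudin and keratin results were lost (adjusted p = 0.129, 0.104 and 0.128), and 3 collagens, 2 claudins and 2 keratins rose. Without DMSO replicate 1, 3 collagens (adjusted p = 0.0219), 2 claudins (0.0219), no keratin and no Sox factor rose, and without R406 replicate 2, 15 collagens rose. Apolipoproteins (2 of 4 rose, adjusted p = 0.0365) lost their result without DMSO replicate 1, when 0 rose, and without R406 replicate 2 (0.0756). Matrix metalloproteinases, cathepsins, guanylate-binding proteins, Wnt ligands, fibroblast growth factors, bone morphogenetic proteins and GATA factors did not pass with all 4 libraries. Falling matrix metalloproteinases passed without DMSO replicate 1 (adjusted p = 0.0278) or R406 replicate 1 (0.0337). No call in these families changed sign under quantile normalization or median centring. Centring moves all log2 changes alike and by little (median −0.0155 before and 0.0121 after), so it could hardly have changed a sign.

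The fall of macrophage genes was followed up with a second list of macrophage genes, fixed before their values were read. The list held 31 genes, and those below 0.5 TPM in both groups were left out. Among these were Cd163, Itgam and Cx3cr1, at 0.223, 0.206 and 0.0745 TPM in DMSO, and Cybb, listed at 0. Such markers were too low in DMSO to show a fall, which limits what the list says of macrophages there. The 19 expressed genes (minimum 0.5 TPM) had a median log2 ratio of −2.79 (quartiles −3.62 and −1.84). Of these, 17 were lower and 2 higher: Alox5ap, which rose to 58.7 TPM, and Lcp1. The ratio used group means plus 0.1 TPM. Its size therefore cannot be set against the log2(TPM + 1) median of the first list. Of 13 members tested with limma, 7 fell and 1 rose over all genes. A shift of all TPM values is argued against by a median of −0.015 over all tested genes, and a loss of all minor cell types alike by a median of −0.121 over 10 endothelial and neural markers (SD 1.27), since these would have had to fall as far as macrophage genes did. Fewer macrophages in the R406 cultures may therefore account for the pattern, which would include part of the Tyrobp, Fcer1g and chemokine falls. Lower expression within the macrophages stays open, since bulk RNA does not separate cell number from expression, and how many of the listed genes fibroblasts express was not tested.

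A second list of endoderm genes was used in the same way for the rise of endoderm and epithelial genes. Of its 16 expressed genes 13 were higher and 3 lower, with a median log2 ratio of 1.36 (quartiles 0.965 and 2.01). The same 0.1 TPM was added for this ratio. Of 13 members tested with limma on log2(TPM + 1), 6 rose and 2 fell over all genes. Spink1 reached 626 TPM in R406, while Rbp4 (log2 −1.91, limma adjusted p = 0.0165) and Foxa1 (−1.15, 0.0424) fell. The loss of macrophage RNA raising all other values is argued against by a median of −0.108 in the fibroblast list (SD 1.03). A larger share of endoderm-like cells with R406 is consistent with these values as a hypothesis. Activation of the same genes within all cells was not tested and stays open.

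The larger R406 peak list was tested against depth. The background pileup was 1.56 times higher in the R406 library, and thinning the R406 pileups to the DMSO background in 20 draws left 32213 to 32431 peaks, 1.52 times the DMSO number against 1.74 before. A deeper R406 library may thus explain part of the surplus and not all of it, although the thinning used only values at called peaks. The share of fragments in peaks, the efficiency of each reaction and the level of FLAG-Nfatc1 stay open, with 1 library per condition and no test of a biological explanation. The highest peaks were mostly shared: 98.0% of the top 100 and 96.2% of the top 5000 DMSO peaks met an R406 peak, and 100% and 95.1% the other way.

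Of genes called higher, 137 had a DMSO peak near an end where 230 would be expected, and of genes called lower 213 against 230. The expectation came from the peak frequency of genes in the same of 10 equal classes of mean expression. The classes used the mean of both groups, while the peaks came from the DMSO library. Genes called higher stood below that mean in DMSO, so the comparison does not match expression in DMSO. Gapdh, commonly among the most abundant transcripts, was listed at 9.65, 15.1, 15 and 19.8 TPM, whereas Actb stood at 786, 711, 573 and 508. Junb was 66.5 and 46.1 TPM in DMSO but 61.2 and 0 in the R406 libraries. Several transcripts followed the replicate number and not the treatment: H1fx (22.8 and 37.9 TPM) and Gm26619 (1230 and 1602) were above 0 only in replicates 1, and Gm10260 (2445 and 3309) only in replicates 2. Rps27 was 3786 and 8807 TPM in DMSO and 8266 and 19717 in R406.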
